A study of Mus musculus with 12 samples.

How the data were processed

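RNA was measured in whole liver of 12 mice, 6 injected with CCl4 and 6 with corn oil, per the labels. Per the labels' protocols, RNA was purified on columns and libraries were made with a stranded total RNA kit. The authors deposited read counts per gene, as whole numbers without normalisation, for each sample and in a table of the series; all 12 columns of that table equalled the files of the samples. Per the submitters' processing notes the genome build was GRCm38. The aligner, counting tool, annotation and use of strand in counting are not given in the sources used here, so antisense and overlapping genes and families of close copies may share reads. The spans of 17 named genes overlap another tested protein-coding gene, among them Pitx3 with Elovl3, Timp1 with Syn1 and Dbp with Sphk2.

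Groups were taken from the sample labels, and replicate numbers only name samples. The files held 36528 numeric gene IDs, of which 10900 had no count in any library. Names came from RefSeq for GRCm38.p6 (31049 IDs) and GENCODE M21 (77 IDs); 5402 IDs had no name and took 2.19% of counts. All replicate pairs differed by more than sampling noise (chi-square per gene of at least 53.4), and within groups Pearson's r of log2 CPM across genes, which are not independent replicates, ran from 0.933 to 0.989. Total counts per library ran from 43027778 to 70375852, so that genes far under 1 CPM rest on few counts. The share of counts of a single library has a 95% Wilson interval, which covers counting error only, as reads without molecular identifiers are not independent molecules.

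Genes were filtered with filterByExpr, scaled by TMM and tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood F test, robust, Benjamini-Hochberg adjustment, threshold 0.05). Log2 CPM used a prior count of 2. The standard error of a log2 fold change was its size divided by the square root of F. Gene lists (34 of pathways and 21 of cell types) were tested with camera in limma 3.58.1 at a preset correlation of 0.01; some genes stand in more than 1 list. Library shares were compared by exact two-sided permutation of 6 against 6 livers, adjusted over 6 measures. Groups, tests, lists, the rule for named genes and the alternatives not marked below as added were chosen before the data were examined. The named genes were 16 fixed genes; the 10 largest rises and 10 largest falls past the threshold with a mean log2 CPM of at least 1, a proper symbol and all livers of a group beyond those of the other; and up to 2 members of each list with the smallest p, plus for pathway lists the called member with the smallest p that went against the majority. This gave 141 genes, of which some are not reported here.

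Alternatives were DESeq2 size factors, upper-quartile scaling, scaling without mitochondrial genes or without the 20 largest genes, DESeq2 1.42.0, limma-voom with quality weights, no filter, a filter of 50 counts in 6 libraries, thinning to the smallest total, a test against 1.5-fold, and leaving out each library; for lists also an estimated correlation, fry and 10000 random lists matched on expression. Sex as a covariate was not run, since all 12 libraries looked male. Added after the data were seen were the removal of a smooth trend in transcript length and then GC content from each library (lowess span 0.3; 13882 of the 16032 tested genes, 86.6%, had a transcript length), the length slope as a covariate, and leaving out the library of each group richest in short transcripts. The scripts were tested on simulated counts for this comparison of 6 against 6 libraries over 16032 genes, with 100 genes changed 1.5-fold and 100 changed 2-fold. Of 98 tested genes changed 1.5-fold 8 were called, of 98 changed 2-fold 39 were called, and 4 unchanged genes were called. With no gene changed 0 were called. Genes were drawn independently and without the length trend of the real libraries. These 0 calls therefore do not measure false calls in the real data. Far fewer genes were changed in the simulation than were called in the data. As the adjustment is stricter with few changed genes, these shares do not give the power of the real comparison.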

Results

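The data were gene-level RNA-seq read counts from whole liver of 12 mice. Of these, 6 had received carbon tetrachloride (CCl4), a solvent that hepatocytes turn into a toxic radical, and 6 had received corn oil, in both cases by intraperitoneal injection 3 times per week for 6 weeks. Repeated CCl4 is a standard way to injure and scar the mouse liver, and the comparison asks how the transcripts of the chronically injured liver differ from those of the oil-injected liver. Total counts per library ran from 43027778 to 70375852, with 52311656 ± 9879136 in the oil group and 62120399 ± 6131709 in the CCl4 group (mean ± SD, n = 6 each). Normalised values below are CPM, counts scaled to a library total of 1000000 after TMM scaling, and coordinates are those of the GRCm38 build.

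Transcripts of the hepatocytes around the central vein were far lower after CCl4, and transcripts of activated stellate cells, monocyte-derived macrophages and dividing cells were higher, as were those of the collagen genes Col1a1, Col1a2 and Col3a1. In whole liver a change in the number of cells of a type cannot be told apart from a change in the level per cell. Of 16032 genes tested with edgeR's quasi-likelihood test, 6256 passed an adjusted p of 0.05, of which 3305 rose and 2951 fell. At a fitted change of at least 2-fold, 1888 rose and 964 fell. All 6 livers of a group lay beyond all 6 of the other for 3207 of the 16032 tested genes (20%), where chance would give 0.216%. The division of calls depended on the scaling: 52.8% of the called genes were rises with TMM and 67.3% with upper-quartile scaling, under which the median of all genes stood at 0.13 on the log2 scale instead of 0.01. Tested against a change of 1.5-fold, 2381 genes passed (1616 risen and 765 fallen). Of 55 gene lists, camera with a preset correlation called 21 risen and 12 fallen; with an estimated correlation 8 and 3 of them passed.

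Genes of pericentral hepatocytes fell. Of the list's 20 measured members 16 fell and 1 rose, with the same counts adjusted over the list alone, and the median log2 fold change was -1.68 (camera adjusted p = 1.17e-23, and adjusted p = 0.000643 with an estimated correlation). Cyp2e1, the P450 enzyme that activates CCl4 (gene ID 13106, chromosome 7, 140763819 to 140774990), fell from 6194 ± 689 CPM in oil to 507 ± 185 CPM in CCl4 (SD, n = 6 each), a 12.2-fold lower level (log2 fold change -3.61 ± 0.23 SE, adjusted p = 1.76e-07). Glul, which encodes glutamine synthetase of the innermost hepatocytes (gene ID 14645, chromosome 1, 153899929 to 153909723), fell 18.4-fold from 761 ± 85.3 to 41.4 ± 7.93 CPM (adjusted p = 1.52e-09). Slc1a2, a glutamate transporter (gene ID 20511, chromosome 2, 102658239 to 102790784), went from 130 ± 23.0 to 0.342 ± 0.0913 CPM, the lowest adjusted p of all genes (2.11e-11). Oat, ornithine aminotransferase, was 19.3-fold lower. Lect2 was the member that rose, 2.10-fold (adjusted p = 0.000387), while Gulo and Rgn, among others, did not pass. Of 20 periportal genes 10 fell and 4 rose (11 and 4 adjusted over the list alone), with a median of -0.59 (adjusted p = 0.00756, and adjusted p = 0.303 with an estimated correlation). Against random lists matched on expression the list did not pass (adjusted p = 0.0930). The amino acid enzymes Tat and Hal fell 3.06-fold and 2.51-fold, and the aldehyde dehydrogenase Aldh1b1 rose 1.81-fold.

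**Figure D1:**
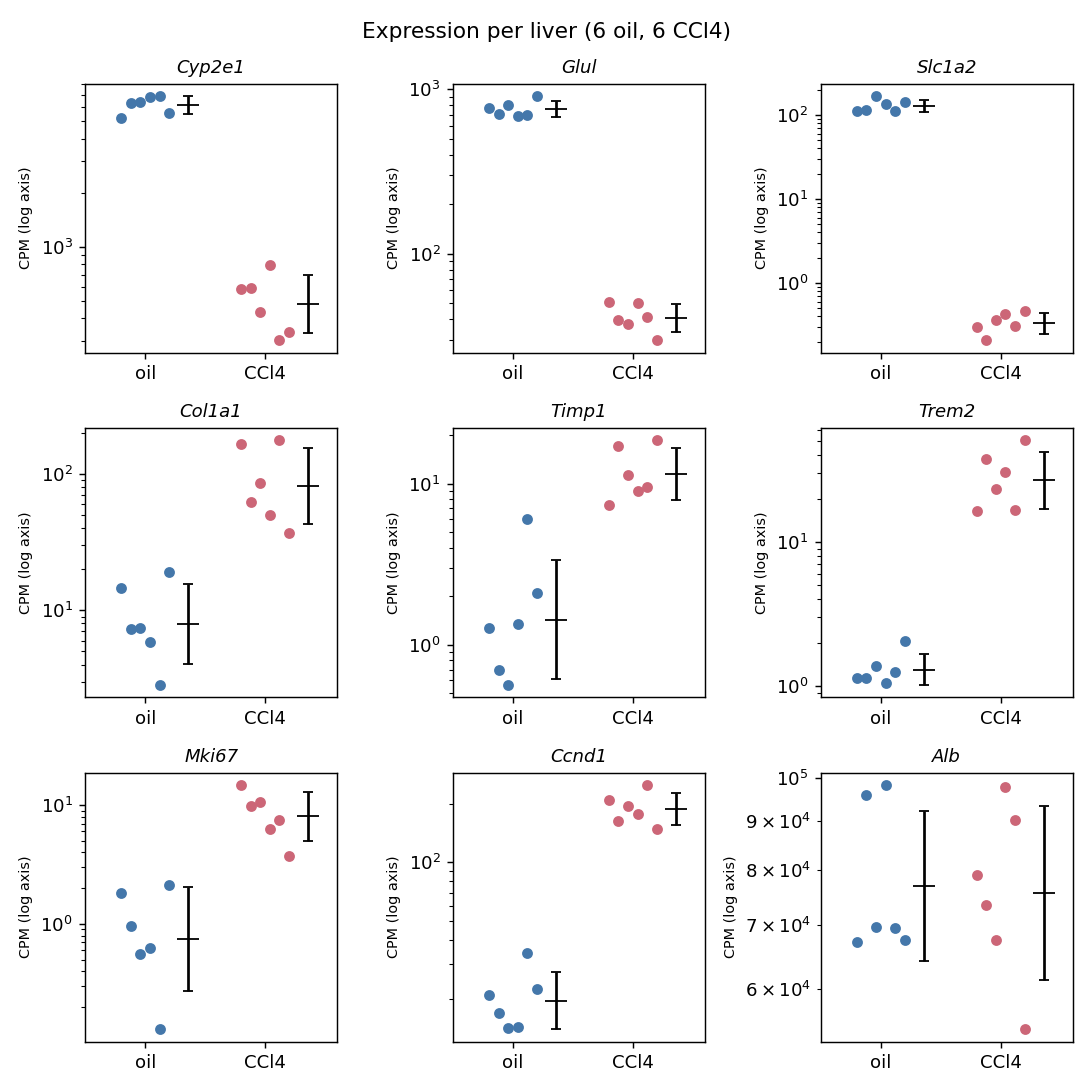
CPM of 9 genes in each liver, on log axes; each point is 1 of 6 oil or 6 CCl4 livers, and the bar beside each group is the mean and SD of the log2 values. Cyp2e1 lay between 5203 and 6906 CPM in oil and between 302 and 793 CPM in CCl4, whereas Alb overlapped between the groups.

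Drug-metabolising cytochrome P450 genes fell in 18 of 30 tested members and rose in 3 (20 and 4 adjusted over the list alone), with a median log2 fold change of -0.73 (adjusted p = 3.80e-09, and adjusted p = 0.0813 with an estimated correlation). Cyp2c38 fell 15.5-fold to 1.88 ± 0.525 CPM. Cyp2a4, a steroid hydroxylase, went the other way, from 0.422 ± 0.195 to 26.9 ± 18.6 CPM (adjusted p = 1.63e-06). Members of the Cyp2a and Cyp2c families are close copies of each other, and counts could be divided between them in ways that are not given in the sources used here.

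Male-biased liver genes, which depend on the pulsed growth hormone of male mice, fell in 13 of 14 members (13 adjusted over the list alone), with a median of -2.53 (adjusted p = 4.44e-15, and adjusted p = 0.0427 with an estimated correlation). Susd4 fell 79.2-fold from 43.8 ± 11.5 to 0.551 ± 0.192 CPM, and Cyp7b1, an oxysterol hydroxylase, fell 14.9-fold from 385 ± 127 to 25.8 ± 13.6 CPM. Elovl3, a fatty acid elongase, fell from 875 ± 397 to 8.17 ± 10.8 CPM; its log2 fold change of -6.74 became -7.86 without CCl4 replicate 1, -7.77 with limma-voom and -6.03 with the length slope as a covariate. Mup20 did not pass. Of 10 tested female-biased genes 3 rose and none fell (3 and 0 adjusted over the list alone), and the list was not shifted (adjusted p = 0.234). Cyp2a4, given above among the P450 genes, and Cyp17a1 were among those that rose. The median of the list was -0.34, its mean was 0.89 and the direction of the test was up. The median was 0.60 without oil replicate 5 and 0.75 without the library of each group richest in short transcripts. All 12 libraries had under 1 CPM of Xist and more than 1 CPM of the Y-linked gene Ddx3y.

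Collagen and other matrix genes rose. Of 17 collagen chains 13 rose and 2 fell (13 and 2 adjusted over the list alone), with a median of 1.53 (adjusted p = 4.61e-06, and adjusted p = 0.279 with an estimated correlation). Col1a1 (gene ID 12842, chromosome 11, 94936224 to 94953042) was 10.1-fold higher, at 96.3 ± 60.3 CPM against 9.48 ± 6.05 CPM (log2 fold change 3.34 ± 0.50 SE, adjusted p = 0.000137). With the length slope of each library as a covariate its log2 fold change was 4.21. Col1a2 was 9.02-fold and Col3a1 7.19-fold higher. Col18a1, whose product lies in basement membranes, fell 1.89-fold, and Col5a3, chosen after its values were seen, also fell. Matrix glycoproteins and proteoglycans rose in 20 of 28 members and fell in none (22 and 0 adjusted over the list alone; median 1.16, adjusted p = 1.44e-11, and adjusted p = 0.0633 with an estimated correlation). Sparc rose 3.97-fold and Efemp2 3.46-fold. Collagen-processing genes rose in 9 of 15 and fell in 2 (10 and 2 adjusted over the list alone; median 0.74, adjusted p = 0.000418, and adjusted p = 0.138 with an estimated correlation). The crosslinking enzymes Lox and Loxl2 rose 7.70-fold and 5.40-fold, and Bmp1, a procollagen protease, fell by 0.59 on the log2 scale. Matrix proteases and their inhibitors rose in 12 of 18 (13 risen and 1 fallen adjusted over the list alone), with a median of 1.75 (adjusted p = 1.92e-08, and adjusted p = 0.0427 with an estimated correlation). Mmp12, macrophage elastase, rose 41.2-fold from 2.09 ± 1.38 to 86.8 ± 26.3 CPM, and Timp1, an inhibitor of these enzymes, rose 6.11-fold; without oil replicate 5 the log2 fold change of Timp1 was 3.33 in place of 2.61, and with limma-voom 3.28.

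Markers of activated stellate cells and myofibroblasts rose in 13 of 14 members (13 adjusted over the list alone), with a median of 2.61 (adjusted p = 1.98e-11, and adjusted p = 0.0189 with an estimated correlation). Of the 14 genes 5 are also in the lists of collagens, crosslinking and proteases. Acta2, smooth muscle actin, rose 6.13-fold (log2 fold change 2.62 ± 0.19 SE), and Pdgfrb rose 2.36-fold. Quiescent stellate markers rose in 6 of 12 and fell in 2 (6 and 2 adjusted over the list alone), and the list did not pass (adjusted p = 0.0805). Within it Des, an intermediate filament gene, rose 2.94-fold and Lrat, which esterifies retinol, 1.56-fold. Muscle also expresses Des, which was at 22.0 CPM in CCl4 replicate 1, the library with most muscle transcripts (292 CPM below the filter on low counts). In the other 5 CCl4 livers Des was at 8.64 to 11.9 CPM, highest in replicate 3, where muscle transcripts summed to 53.7 CPM. Without CCl4 replicate 6 the list passed (adjusted p = 0.0491), but not with an estimated correlation (adjusted p = 0.166). Lrat did not pass without oil replicate 1 (adjusted p = 0.0565). Portal fibroblast markers rose in 9 of 11 (9 adjusted over the list alone; median 1.30, adjusted p = 2.49e-05, and adjusted p = 0.0180 with an estimated correlation). Dpt rose 4.53-fold and Cd34 3.15-fold. Of 16 genes of TGF-beta signalling 6 rose and 1 fell (6 and 1 adjusted over the list alone), without a shift of the list (adjusted p = 0.302). Tgfb1 rose 1.76-fold, Tgfb3 2.41-fold and the decoy receptor Bambi 2.18-fold, and Smad4 fell 1.26-fold, but not past the threshold without oil replicate 3 (adjusted p = 0.0512), with upper-quartile scaling (adjusted p = 0.106) or with no filter (adjusted p = 0.0504).

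**Figure D2:**
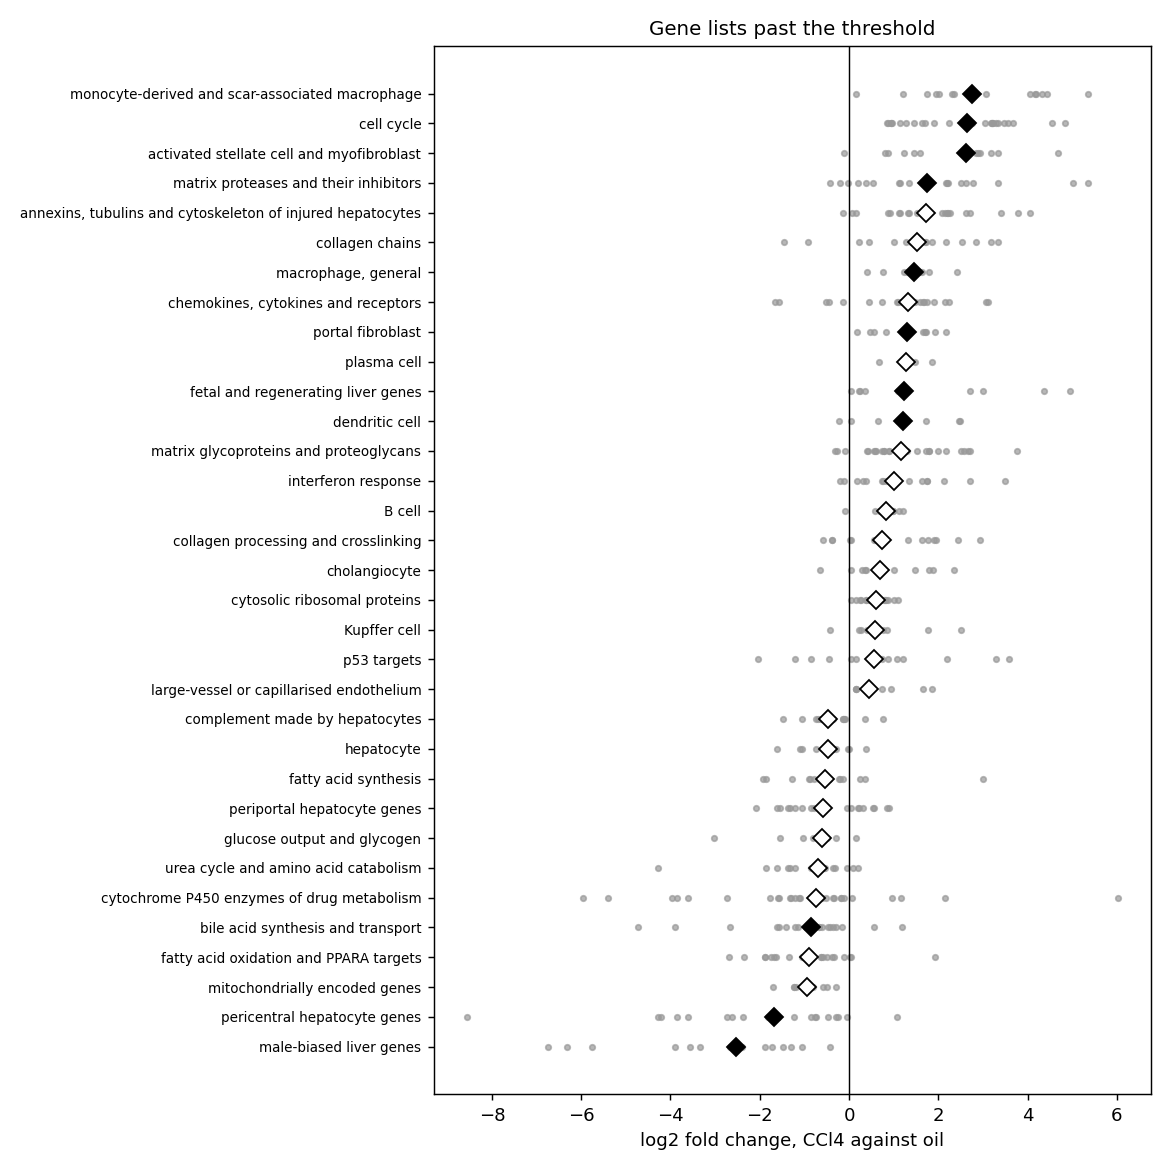
Log2 fold change, CCl4 against oil, for the 33 gene lists past the threshold; grey points are tested genes and diamonds are list medians, filled where the list also passed with an estimated correlation. Medians ran from -2.53 for male-biased genes to 2.75 for monocyte-derived and scar-associated macrophages.

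Macrophage transcripts rose. Markers of monocyte-derived and scar-associated macrophages rose in 14 of 15 members (14 adjusted over the list alone), with a median of 2.75 (adjusted p = 1.17e-23, and adjusted p = 0.0180 with an estimated correlation). Trem2, a lipid receptor of these cells, rose 21.7-fold from 1.34 ± 0.375 to 29.2 ± 13.4 CPM (adjusted p = 3.45e-07). Ccr2, the monocyte chemokine receptor, rose 8.34-fold and Spp1, osteopontin, 5.08-fold. General macrophage markers rose in 10 of 11 (11 adjusted over the list alone; median 1.46, adjusted p = 2.91e-10, and adjusted p = 0.0189 with an estimated correlation). Cd68 rose 5.37-fold and Ctss 3.03-fold. Markers of Kupffer cells, the resident macrophages, rose in 4 of 9 (6 adjusted over the list alone; median 0.58, adjusted p = 0.00745, and adjusted p = 0.138 with an estimated correlation). Marco rose 5.66-fold and Cd5l 3.40-fold (log2 fold change 1.77, and 1.15 with the length slope as a covariate), whereas Clec4f was at 118 ± 43.6 CPM against 78.7 ± 17.7 CPM and did not pass (adjusted p = 0.0597). It did without CCl4 replicate 1 or 5 or oil replicate 2 or 5 (adjusted p = 0.0179 to 0.0480), with upper-quartile scaling (adjusted p = 0.0283) and with limma-voom (adjusted p = 0.0116). With the length slope as a covariate the log2 fold change of Clec4f was 0.08 in place of 0.58. Dendritic cell markers rose in 6 of 8 (6 adjusted over the list alone; median 1.20, adjusted p = 0.00512, and adjusted p = 0.0489 with an estimated correlation). B cell markers rose in 6 of 8 (6 adjusted over the list alone; adjusted p = 0.0284, and adjusted p = 0.166 with an estimated correlation). Plasma cell markers rose in 4 of 5 (4 adjusted over the list alone; adjusted p = 0.0220, and adjusted p = 0.166 with an estimated correlation). The B cell list did not pass without oil replicate 5 (adjusted p = 0.0559), nor the plasma cell list with the length and GC trend removed (adjusted p = 0.0565). The B cell list also did not pass without the library of each group richest in short transcripts (adjusted p = 0.0621). Against matched random lists none of these 3 passed (adjusted p = 0.0645 for dendritic cells, 0.288 for B cells and 0.0832 for plasma cells). Chemokines, cytokines and their receptors rose in 17 of 24 and fell in 3 (18 and 4 adjusted over the list alone; adjusted p = 3.75e-05, and adjusted p = 0.138 with an estimated correlation). Cxcl14 rose 8.64-fold and Il1b fell 3.16-fold. Interferon-response genes rose in 16 of 20 (16 adjusted over the list alone; median 1.01, adjusted p = 4.09e-07, and adjusted p = 0.131 with an estimated correlation). Oas1a rose 6.53-fold and Irf7 3.11-fold.

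Every one of the 26 cell cycle genes rose (26 adjusted over the list alone), with a median of 2.65 (adjusted p = 2.56e-20, and adjusted p = 0.0180 with an estimated correlation). Ccnd1, cyclin D1, rose 9.24-fold from 20.5 ± 7.61 to 190 ± 36.2 CPM, and the proliferation marker Mki67 rose 8.32-fold from 1.03 ± 0.773 to 8.79 ± 3.86 CPM (log2 fold change 3.06, and 3.77 with the length slope as a covariate). Targets of p53 rose in 9 of 16 and fell in 1 (10 and 1 adjusted over the list alone; median 0.57, adjusted p = 0.00954, and adjusted p = 0.0555 with an estimated correlation). Phlda3 rose from 0.820 ± 0.257 to 9.80 ± 3.76 CPM and Eda2r 9.82-fold, and Trp53inp1 fell 4.11-fold. Annexins, tubulins and other cytoskeletal genes of injured hepatocytes rose in 19 of 22 (19 adjusted over the list alone; median 1.72, adjusted p = 8.23e-16, and adjusted p = 0.0555 with an estimated correlation). Anxa2 rose 10.6-fold and Anxa5 3.28-fold. In whole liver this rise cannot be assigned to hepatocytes, since macrophage and stellate cell markers rose too and the list shares Cd63 with that of scar-associated macrophages. Genes of fetal and regenerating liver rose in 7 of 11 (7 adjusted over the list alone; median 1.22, adjusted p = 0.000355, and adjusted p = 0.0189 with an estimated correlation). Prom1 rose 20.7-fold and Afp, alpha-fetoprotein, 7.95-fold. Cholangiocyte markers rose in 5 of 10 (5 risen and 1 fallen adjusted over the list alone; adjusted p = 0.00512, and adjusted p = 0.131 with an estimated correlation), but not against matched random lists (adjusted p = 0.0802). Spp1, which macrophages also express, and Tspan8 rose, while Krt19, a keratin of bile ducts, was at 4.04 ± 0.673 CPM against 3.90 ± 1.69 CPM.

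**Figure D3:**
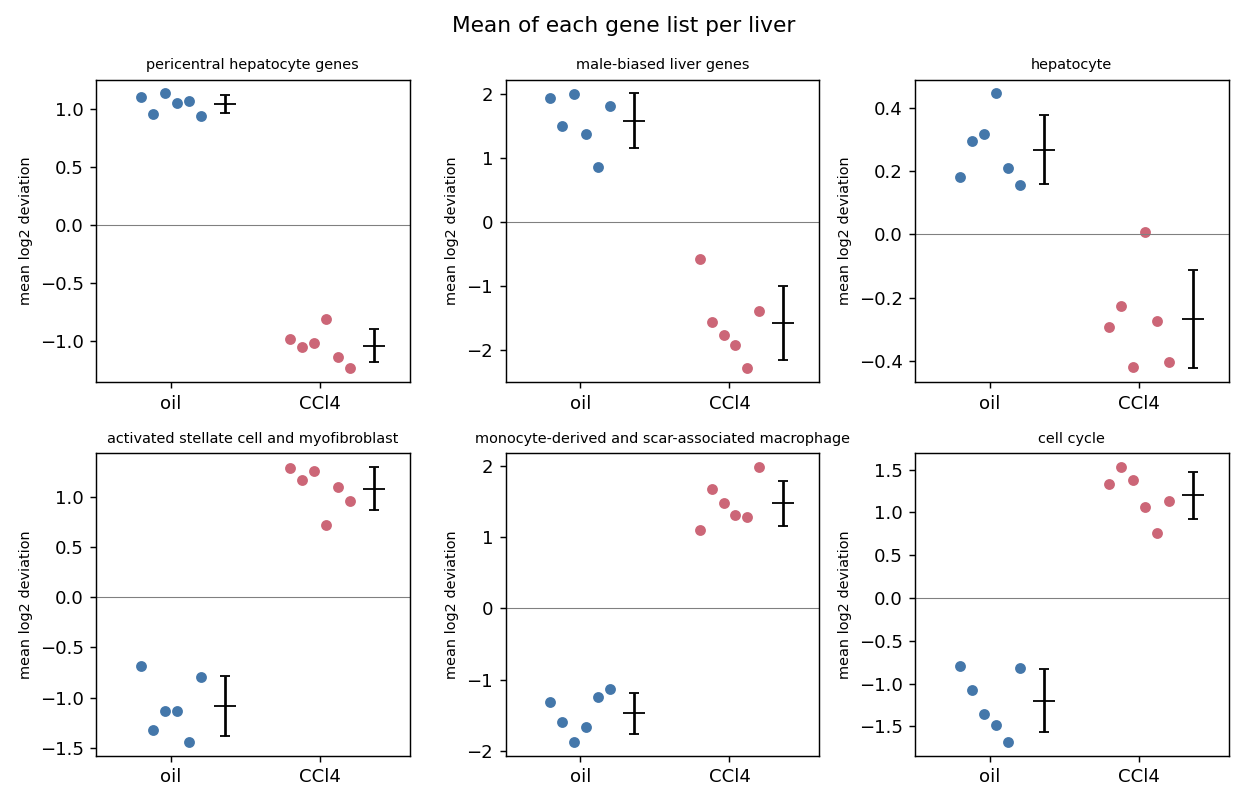
Mean log2 deviation from each gene's average over 12 livers, for 6 gene lists; points are single livers and bars the mean and SD of 6 livers per group. Pericentral, male-biased and hepatocyte genes were lower and stellate, macrophage and cell cycle genes higher in all 6 CCl4 livers than in any oil liver.

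Several lists of hepatocyte metabolism fell. Bile acid synthesis and transport fell in 16 of 22 and rose in 1 (18 and 1 adjusted over the list alone; median -0.85, adjusted p = 5.74e-08, and adjusted p = 0.0427 with an estimated correlation). Cyp8b1, the sterol 12-hydroxylase, fell 26.6-fold from 539 ± 182 to 20.3 ± 12.1 CPM, and Abcc4, an efflux transporter, rose 2.29-fold. Fatty acid oxidation and PPARA targets fell in 17 of 22 and rose in 1 (18 and 1 adjusted over the list alone; median -0.90, adjusted p = 4.70e-08, and adjusted p = 0.102 with an estimated correlation). Acaa1b, an enzyme of peroxisomal oxidation, fell 6.42-fold, and the hormone Fgf21 rose 3.79-fold, though not past the threshold with the length slope as a covariate (adjusted p = 0.0813). Fatty acid synthesis fell in 8 of 16 and rose in 1 (9 and 1 adjusted over the list alone; median -0.54, adjusted p = 0.0272, and adjusted p = 0.495 with an estimated correlation). Dgat2 fell 1.85-fold and Pnpla3 rose 7.95-fold (log2 fold change 2.99, and 3.59 with the length slope as a covariate). Urea cycle and amino acid catabolism fell in 15 of 20 (15 adjusted over the list alone; median -0.69, adjusted p = 6.15e-09, and adjusted p = 0.0595 with an estimated correlation), with Prodh 3.64-fold lower. Glucose output and glycogen genes fell in 7 of 10 (7 adjusted over the list alone; median -0.60, adjusted p = 0.00213, and adjusted p = 0.138 with an estimated correlation). G6pc, glucose-6-phosphatase, fell 8.10-fold. Against matched random lists neither fatty acid synthesis nor glucose output passed (adjusted p = 0.150 for both). Mitochondrially encoded genes fell in 11 of 12 (11 adjusted over the list alone; median -0.94, adjusted p = 6.86e-06, and adjusted p = 0.0824 with an estimated correlation); ND1 fell 1.96-fold. Cholesterol synthesis was not shifted (4 of 23 fell, and 0 adjusted over the list alone; adjusted p = 0.11), and its member Nsdhl, a sterol dehydrogenase, passed at adjusted p = 0.0328. Nsdhl did not pass without CCl4 replicate 2, 4 or 6 or any oil replicate but 1 and 5 (adjusted p between 0.0517 and 0.0711), with upper-quartile scaling (adjusted p = 0.0828) or with the length slope as a covariate (adjusted p = 0.167). The list passed without CCl4 replicate 5 (adjusted p = 0.0279) or oil replicate 5 (adjusted p = 0.0160) and with no filter (adjusted p = 0.0389). It also passed without the library of each group richest in short transcripts (adjusted p = 0.0115), but not with an estimated correlation (adjusted p = 0.788).

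Among secreted liver products Alb, serum albumin, was at 77060 ± 15610 CPM in CCl4 and 78020 ± 14780 CPM in oil (log2 fold change -0.02 ± 0.16 SE, adjusted p = 0.939). Plasma proteins and clotting factors fell in 8 of 24 and rose in 3 (8 and 3 adjusted over the list alone), without a shift (adjusted p = 0.151). F7 fell 1.69-fold. Ahsg, fetuin-A, rose from 8946 ± 806 to 13440 ± 1518 CPM, a call that ended with the transcript length and GC trend removed (adjusted p = 0.0597). Complement genes of hepatocytes fell in 7 of 17 and rose in 2 (8 and 2 adjusted over the list alone; adjusted p = 0.0215, and adjusted p = 0.279 with an estimated correlation). C8b fell 2.07-fold and Masp2 1.54-fold, and Mbl2 rose 1.69-fold. Mbl2 did not pass without CCl4 replicate 2, 4 or 6 or any oil replicate but 5 (adjusted p = 0.0644 to 0.0976). With the length slope as a covariate its log2 fold change was 0.20 in place of 0.76 (adjusted p = 0.201). Hepatocyte markers fell in 7 of 12 (7 adjusted over the list alone; median -0.47, adjusted p = 0.00512, and adjusted p = 0.166 with an estimated correlation). Against matched random lists neither complement genes (adjusted p = 0.585) nor hepatocyte markers (adjusted p = 0.683) passed. Of 19 acute phase genes 2 rose and 3 fell (2 and 3 adjusted over the list alone; adjusted p = 0.515). Il1rn, the interleukin-1 receptor antagonist, rose 5.18-fold and Lbp fell 1.86-fold.

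Lists of stress, iron and clock genes held both rises and falls. NRF2 targets and glutathione enzymes rose in 11 of 27 and fell in 5 (11 and 8 adjusted over the list alone; adjusted p = 0.0921). Gstm3 rose 6.76-fold and Srxn1 2.72-fold, and Me1 fell 2.25-fold. Without CCl4 replicate 6 the list passed (adjusted p = 0.0492), but not with an estimated correlation (adjusted p = 0.475). With the length and GC trend removed its median log2 fold change was 0.03 in place of 0.27. The stress genes Trib3 and Ddit3 rose 5.71-fold and 3.49-fold and Herpud1 fell 1.67-fold, in a list of 16 with 3 rises and 1 fall (2 and 1 adjusted over the list alone; adjusted p = 0.0548). That list passed without CCl4 replicate 1, 2 or 3 or oil replicate 5 or 6 (adjusted p = 0.0186 to 0.0480). With an estimated correlation it did not (adjusted p = 0.573). Of 17 circadian clock genes 5 rose and 6 fell (6 and 6 adjusted over the list alone; adjusted p = 0.293), with a median of -0.21, a mean of 0.08 and a test direction of down. Dbp, an output of the clock, rose from 1.88 ± 0.508 to 22.5 ± 16.0 CPM, and Nfil3 and Cry1 fell 3.10-fold and 2.73-fold. Of 15 immediate early genes 2 rose and 5 fell (2 and 5 adjusted over the list alone; adjusted p = 0.0535). Ier3 rose 4.31-fold and Fosb fell to 0.758 ± 0.521 CPM from 26.8 ± 20.9 CPM. The list passed without CCl4 replicate 4 or 6 or oil replicate 1, 3 or 5 (adjusted p = 0.00277 to 0.0491). It did not with an estimated correlation (adjusted p = 0.692) or with fry (adjusted p = 0.1365). Iron genes (1 risen and 4 fallen of 14, and 1 and 3 adjusted over the list alone; adjusted p = 0.787) and YAP targets (3 and 4 of 13, and 3 and 5 adjusted over the list alone; adjusted p = 0.933) were not shifted. For YAP targets the median was 0.07, the mean -0.04 and the direction of the test down; for iron genes the median was -0.06, the mean 0.13 and the direction also down. With 1 library left out the medians ran from -0.05 to 0.11 for YAP targets and from -0.16 to 0.00 for iron genes. MHC class II genes rose in 6 of 10 (8 adjusted over the list alone), and the list did not pass (adjusted p = 0.0534). It passed without CCl4 replicate 5 or oil replicate 1, 2 or 4 (adjusted p = 0.0216 to 0.0453), but not with an estimated correlation (adjusted p = 0.495).

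Endothelial genes of large or capillarised vessels rose in 5 of 10 (5 adjusted over the list alone; adjusted p = 0.00749, and adjusted p = 0.131 with an estimated correlation), with Ly6a at 3.65-fold, but the list did not pass against matched random lists (adjusted p = 0.122). Sinusoidal endothelial markers were not shifted (1 risen and 2 fallen of 12, and 1 and 1 adjusted over the list alone; adjusted p = 0.817). Lyve1 rose 1.68-fold and Kdr fell 1.74-fold, but not past the threshold without CCl4 replicate 2 (adjusted p = 0.0506) or with the length slope as a covariate (log2 fold change -0.40 in place of -0.80, adjusted p = 0.0633). T cell markers were not shifted (2 risen and 1 fallen of 11, and 2 and 1 adjusted over the list alone; adjusted p = 0.817), with Cd8b1 2.68-fold higher and Cd4, which Kupffer cells and dendritic cells can also express, 3.77-fold lower. NK cell (0 risen and 1 fallen of 7), neutrophil (1 and 0 of 6), mesothelial (0 and 0 of 7) and erythroid lists (2 and 1 of 7) did not pass, at adjusted p between 0.705 and 0.933; the erythroid list did against matched random lists (adjusted p = 0.00719). Adjusted over the list alone these counts were 0 and 0, 1 and 0, 0 and 0, and 4 and 1. The test direction was down for NK cells (median 0.20, mean 0.05) and for neutrophils (median -0.14, mean 0.02). With 1 library left out these medians ran from -0.04 to 0.30 for NK cells and from -0.37 to 0.48 for neutrophils, the highest without oil replicate 4. The NK gene that fell was Prf1, perforin (2.19-fold lower, adjusted p = 0.0353), which did not pass without CCl4 replicate 3, 4, 5 or 6 or oil replicate 2, 3 or 4 (adjusted p = 0.0530 to 0.0958). Nor did it with upper-quartile scaling (adjusted p = 0.0592), no filter (0.0526), the length slope as a covariate (0.0622) or without the library of each group richest in short transcripts (0.0520). The neutrophil gene that rose was Retnlg (2.45-fold), which did not pass with the trend removed (adjusted p = 0.0778). Of 3 tested fat cell genes Fabp4 rose 5.86-fold (log2 fold change 2.55, and 1.77 with the length slope as a covariate) and Cfd fell (-2.86 on the log2 scale, and -4.21 without CCl4 replicate 3), with a list median and mean of -0.15 and a test direction of up (adjusted p = 0.817). Cela1, the 1 tested member of the acinar pancreas list, did not pass (adjusted p = 0.262) except without CCl4 replicate 1 (adjusted p = 0.0478). Mylpf, the 1 tested member of the skeletal muscle list, rose 4.65-fold (adjusted p = 0.0403). Its adjusted p was 0.191, at a log2 fold change of 0.94 in place of 2.22, without CCl4 replicate 1, and between 0.0566 and 0.0758 without CCl4 replicate 3 or any 1 oil replicate. With limma-voom the log2 fold change was 1.13 (adjusted p = 0.141), and it did not pass with no filter (adjusted p = 0.0830) or with the trend removed (adjusted p = 0.0620).

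Among the genes chosen for size of change, with all 6 livers of a group beyond all 6 of the other, the largest rises included S100g, a calcium-binding protein (0.121 ± 0.0566 to 14.1 ± 6.48 CPM) and Akr1c18, a steroid reductase (0.0784 ± 0.0836 to 10.9 ± 4.70 CPM). They also included Ly6d (1.81 ± 1.55 to 165 ± 79.5 CPM) and Slc7a11, a cystine transporter (0.319 ± 0.457 to 17.9 ± 7.30 CPM). Atp13a4 was at 6.61 ± 2.97 CPM in CCl4 and at 0.0234 CPM or less in 5 of 6 oil livers, so that its fitted fold depends on the prior count. Wfdc3, Atp13a4, Sprr1a and Slc7a11 had their highest oil value in oil replicate 1. Without it their log2 fold changes were 7.70, 9.27, 8.60 and 6.85 in place of 7.01, 6.00, 5.74 and 5.76. Of the other largest rises Akr1c18, S100g, Ly6d and Mmp12 also had their highest oil value in that library, and Cyp2a4 and Tnni2 did not. Tnni2, a troponin of skeletal muscle, was at 21.3 CPM in CCl4 replicate 1, and without that library its log2 fold change was 3.76 in place of 5.53. It was at 5.29 CPM in CCl4 replicate 3, the other library with muscle transcripts, and at 0.225 to 0.769 CPM in the other 4 CCl4 livers. With the length slope as a covariate the log2 fold changes of Wfdc3, S100g, Ly6d and Tnni2 were 6.13, 6.27, 5.89 and 6.51 in place of 7.01, 6.86, 6.51 and 5.53. With limma-voom those of Atp13a4, Sprr1a and Tnni2 were 7.36, 7.98 and 3.57, and that of Wfdc3 was 6.32 without the library of each group richest in short transcripts. The largest falls included 5 major urinary protein genes, a family of near-identical copies on chromosome 4, so that their separate counts are uncertain. Mup11 fell from 1629 ± 993 to 1.05 ± 1.05 CPM and Mup7 from 1458 ± 720 to 20.3 ± 26.6 CPM. Without CCl4 replicate 1 their log2 fold changes were -11.24 and -7.22 in place of -10.60 and -6.16, and with limma-voom that of Mup7 was -7.14. Fitm1, a lipid droplet protein, fell from 38.2 ± 4.64 to 0.542 ± 0.350 CPM. Pitx3 fell from 40.4 ± 18.8 to 0.321 ± 0.302 CPM (log2 fold change -6.98, -7.71 with limma-voom and -6.32 with the length slope as a covariate), but its annotated span on chromosome 19 (46135281 to 46148325) shares 414 bases with Elovl3 (46131897 to 46135694), and whether counting used the strand is not given in the sources used here. For the same reason the counts of S100g, Timp1, Ccnd1, Acaa1b, Masp2, Lect2 and Dbp are uncertain, as their spans overlap Ctps2, Syn1, LTO1, Dlec1, Tardbp, Fbxl21 and Sphk2. Sphk2 was at 42.7 CPM in oil and 41.0 CPM in CCl4. Fbxl21 was at 4.73 and 6.70 CPM, and Syn1 at 0.925 and 1.57 CPM. These changes were far smaller than the rises of Dbp, Lect2 and Timp1, which argues against shared reads as the source of those rises. For S100g, Ccnd1, Acaa1b and Masp2, which moved in the direction of the overlapping gene, this stays open.

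The makeup of the libraries also differed. The 10 largest genes took 20.9 ± 1.10% of counts in CCl4 and 17.8 ± 0.972% in oil, and mitochondrially encoded genes 2.93 ± 0.577% against 5.07 ± 0.940% (SD, n = 6 each). For both the exact two-sided permutation test gave p = 0.00217, the smallest that 924 splits allow (adjusted p = 0.00649). Ribosomal protein genes took 0.470 ± 0.199% against 0.251 ± 0.0661% (exact permutation p = 0.0152, adjusted p = 0.0303). That call ended when any of 6 libraries was left out, CCl4 replicate 6 or an oil replicate other than 5 (exact permutation, adjusted p = 0.0571 to 0.0693). The list of ribosomal protein genes rose in 9 of 24 (12 adjusted over the list alone; adjusted p = 0.0238, and adjusted p = 0.692 with an estimated correlation). It no longer passed after the transcript length and GC trend of each library was removed (median 0.24 in place of 0.60, adjusted p = 0.157) or without CCl4 replicate 6 (adjusted p = 0.0684) or oil replicate 6 (adjusted p = 0.0582). Total counts, genes detected and the haemoglobin share did not differ past the threshold (exact permutation, adjusted p = 0.0857, 0.110 and 0.0844, n = 6 each). Without oil replicate 6 the exact permutation adjusted p of total counts was 0.0260, and without CCl4 replicate 1 or 5 that of haemoglobin was 0.0455 or 0.00974 (exact permutation). The 6 skeletal muscle genes below the filter on low counts summed to 292 CPM in CCl4 replicate 1 and 53.7 CPM in CCl4 replicate 3. The 9 acinar pancreas genes below it summed to 364 CPM in CCl4 replicate 5 and 97.0 CPM in CCl4 replicate 3. Libraries varied in the balance of short and long transcripts, and this varied within both groups. The slope of the log2 deviation per doubling of length ran from -0.38 in CCl4 replicate 6 to 0.16 in CCl4 replicate 5, and from -0.15 in oil replicate 5 to 0.25 in oil replicate 6. The group means differed by -0.19 (exact two-sided permutation test, p = 0.102, n = 6 each).

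**Figure D4:**
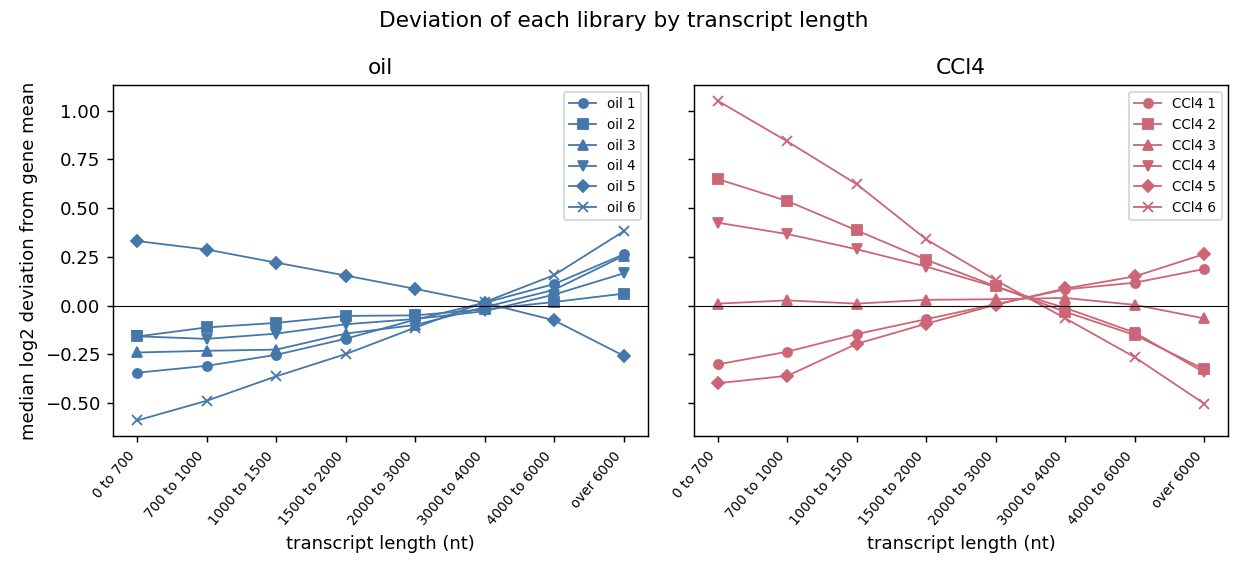
Median log2 deviation of tested genes from their mean over 12 libraries, by transcript length class in nucleotides, with a line per library. Transcripts of up to 700 nucleotides stood at 1.05 in CCl4 replicate 6 and at -0.59 in oil replicate 6.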

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

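The tests of a mislabelled library, of the sex of the mice, of the hepatocyte share, of the time of collection, and of the length trend for male-biased and clock genes were chosen after the values they concern had been seen. Over 404 groups of 6 values, 27 had a sample far from the other 5 by Dixon's criterion, where chance gives about 1 in 20, or 20.2; most of the flags were in oil replicate 5.

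In oil replicate 5 the following lay below the other 5 oil livers: Pitx3 (7.93 CPM), Elovl3 (205 CPM), Bmp1 (82.4 CPM), Nsdhl (66.4 CPM), G6pc (820 CPM), Masp2 (257 CPM), Kdr (12.8 CPM), Cd4 (0.286 CPM) and Cd22 (0.494 CPM), and the mean log2 deviations of bile acid synthesis and transport (0.33), fatty acid synthesis (-0.53) and the circadian clock (-0.61). Its ribosomal protein share of 0.377% (Wilson interval 0.375 to 0.379%) and haemoglobin share of 0.0366% (0.0360 to 0.0372%) lay above the others. The trend in transcript length and GC content is excluded as the whole cause, since after its removal oil replicate 5 still stood apart in 9 of 12 of these genes and lists. A CCl4 library under an oil label is also argued against, since its pericentral score of 1.06 lay far above the highest CCl4 liver, at -0.81. No biological explanation was tested, as the labels give no further grouping of the oil mice.

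Other oil values far from the rest were Atp13a4 in replicate 1 (0.550 CPM), Ahsg in replicate 1 (7392 CPM), Spp1 in replicate 3 (19.8 CPM), Ctss in replicate 3 (28.2 CPM) and Cd8b1 in replicate 6 (0.0309 CPM). In the CCl4 group they were Des (22.0 CPM), Krt19 (2.76 CPM) and Prom1 (4.67 CPM) in replicate 1, Aldh1b1 in replicate 6 (88.2 CPM), Cd8b1 in replicate 5 (0.238 CPM) and Cfd in replicate 3 (0.419 CPM). CCl4 replicate 4 was highest for fatty acid oxidation (mean log2 deviation 0.0019, others -0.69 to -0.48) and for plasma proteins (0.15, others -0.22 to -0.09).

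Genes outside the tests, below the filter on low counts, held a signal of other tissues. The 9 acinar pancreas genes below the filter summed to 97.0 CPM in CCl4 replicate 3 and 364 CPM in CCl4 replicate 5, against at most 27.9 CPM in an oil library (replicate 1). The 6 skeletal muscle genes summed to 292 CPM in CCl4 replicate 1 and 53.7 CPM in CCl4 replicate 3, against at most 0.903 CPM in oil.

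The fall of male-biased genes was weighed against technical explanations. Female mice in the CCl4 group are excluded, since 12 of 12 libraries had the male pattern of Xist and Ddx3y. A lower share of hepatocytes, if even across the liver, would lower both lists alike. The male-biased score minus the hepatocyte score differed by -2.63 on the log2 scale (CCl4 minus oil, n = 6 each, exact permutation p = 0.00217, the smallest possible). This comparison does not cover an uneven loss of hepatocytes. Pericentral genes fell more (median log2 fold change -1.68) than hepatocyte markers (-0.47). The length and GC trend is argued against as well, with a median of -2.71 after its removal (adjusted p = 6.62e-14). An effect of CCl4 on these genes stays open, and no measurement here tested how it would arise.

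Clock genes changed in opposite directions. Of 9 genes assigned to an arm driven through E-boxes 5 rose and none fell (median log2 fold change 1.19). Of 6 assigned to an arm repressed by REV-ERB all 6 fell (median -1.55). The arms were assigned after the values were seen, so the split between them cannot count as a test. What stands without the arms is that 5 clock genes rose and 6 fell. The length and GC trend is argued against, since 11 of 11 called clock genes kept their direction and call after its removal. Collection of the groups at different times of day could also give rises and falls among clock genes. It cannot be told apart from an effect of CCl4, because the labels give no time of collection. The difference of 2.74 between the medians of the assigned arms does not decide this.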

How the results depend on the processing

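The 2 settings that adjust for transcript length and the setting that leaves out the library of each group richest in short transcripts were chosen after the data were seen; the others were planned. Sex as a covariate was not run, as all 12 libraries looked male. No named gene and no list turned its direction with a call on either side, and 108 of 141 named genes and 23 of 55 lists kept direction and side of the threshold in all settings run for them. Tested against a change of 1.5-fold, 2381 genes passed in place of 6256 (1616 risen and 765 fallen), by construction of that test. With an estimated correlation 8 lists rose and 3 fell, in place of 21 and 12. That setting allows for the correlation measured within a list, which was 0.666 for collagen chains and 0.605 for ribosomal proteins, against a preset of 0.01. For p53 targets, whose call also ended, it was -0.009, so that a higher correlation is not the whole cause. Against random lists matched on expression 10 lists no longer passed: markers of hepatocytes (adjusted p = 0.683), B cells (0.288), plasma cells (0.0832), cholangiocytes (0.0802), dendritic cells (0.0645) and large-vessel endothelium (0.122), and genes of complement (0.585), fatty acid synthesis (0.150), glucose output (0.150) and periportal hepatocytes (0.0930). Another 6 did: MHC class II (adjusted p = 0.0497), NRF2 (0.00385), erythroid (0.00719), immediate early (0.000733), quiescent stellate (0.00550) and unfolded protein genes (0.00660). These random lists take no account of correlation between the genes of a list. With no filter MHC class II, NRF2, cholesterol synthesis, immediate early, quiescent stellate and unfolded protein genes passed (adjusted p = 0.0149 to 0.0389). With fry MHC class II, NRF2, TGF-beta, quiescent stellate and unfolded protein genes passed (adjusted p = 4.66e-05 to 0.01003). That test asks whether a list changed at all, whereas camera and the random lists compare it with other genes. With the trend removed immediate early (adjusted p = 0.0499), quiescent stellate (0.0435) and plasma protein genes (0.0458) passed. Without CCl4 replicate 6 and oil replicate 5 together NRF2 (adjusted p = 0.0224), cholesterol synthesis (0.0115), immediate early (0.00285) and unfolded protein genes (0.0268) did. None of the lists that gained a call in these settings passed with an estimated correlation (adjusted p = 0.166 to 0.894). Other counts stayed within 1.5 times: up to 8729 genes with limma-voom, and 6186 with upper-quartile scaling, where 4164 rose and 2022 fell. With the trend removed 6952 genes passed (3549 risen and 3403 fallen), and without CCl4 replicate 6 and oil replicate 5 together 6879. Leaving out 1 library gave 5238 genes (without CCl4 replicate 2) to 7514 (without oil replicate 5). Among shares, the CCl4 minus oil difference over libraries left out ran from 0.149 to 0.257 percentage points for ribosomal proteins, from 0.0194 to 0.0405 for haemoglobin, and from 7.95 to 13.4 (in 1000000 counts) for total counts; the cause was not tested. Outside the 1.5-fold test 12 named genes lost their call in some setting, among them Mylpf, a muscle gene, which did without CCl4 replicate 1 (log2 fold change 0.94 in place of 2.22). Depth limits genes under 1 CPM, so that a missed call does not show an unchanged gene. In simulated data 39 of 98 genes changed 2-fold were called. There only 100 genes were changed 2-fold and 100 by 1.5-fold, far fewer than were called here, which makes the adjustment stricter. That share therefore does not measure the power of this comparison.

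Of 100 splits of the 12 livers into 6 and 6, drawn from 462, the real one gave 6256 genes and 1 split gave as many, the real one itself, so that chance is excluded at that level. The highest other split gave 3639 genes and put CCl4 replicates 1 and 5 with oil replicates 1, 3, 4 and 6; these are the libraries with more long transcripts, which points to a structure of the samples along that balance. The median of the other splits was 0 genes.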

Other observations

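Among immune genes named by the rule but not described so far, Siglech and Flt3, markers of plasmacytoid and other dendritic cells, rose 5.48-fold and 5.59-fold, from 0.150 ± 0.0482 to 0.840 ± 0.178 CPM and from 0.185 ± 0.0790 to 1.04 ± 0.109 CPM (SD, n = 6 each). The B cell genes Cd22 and Cd79b rose 2.31-fold and 2.18-fold, and the plasma cell genes Jchain and Prdm1 2.80-fold and 2.43-fold. Cyp17a1, a steroid hydroxylase, rose 5.03-fold from 4.02 ± 1.22 to 20.2 ± 8.52 CPM. Id1, a target of BMP signals, rose 3.51-fold, while Tfr2, a transferrin receptor of hepatocytes, fell 1.73-fold. Axl, a receptor tyrosine kinase, rose 2.32-fold and the phosphatase gene Ptpn14 2.20-fold. Alas2, the haem synthesis enzyme of red cells, fell 1.84-fold, but all of its annotated span overlaps Apex2, so that its counts are uncertain. Apex2 was at 7.23 CPM in oil and 7.25 CPM in CCl4, and Alas2 at 160 and 86.8 CPM. These values argue against reads of Apex2 as the source of the fall. Of the same list Hba-a2, an alpha globin gene, rose 1.94-fold (adjusted p = 0.0227). It did not pass without CCl4 replicate 2 (adjusted p = 0.0578) or 6 (0.0547), without oil replicate 1 (0.0538) or 6 (0.0521), or with the length slope as a covariate (log2 fold change 0.26 in place of 0.96, adjusted p = 0.124).

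The nuclear RNAs Malat1 and Neat1 varied within both groups. Malat1 ran from 35.5 CPM in CCl4 replicate 6 to 263 CPM in CCl4 replicate 1, and from 47.1 CPM in oil replicate 5 to 332 CPM in oil replicate 1 (CPM of raw totals). Neat1 ran from 82.1 CPM in CCl4 replicate 4 to 411 CPM in CCl4 replicates 1 and 5, and from 105 CPM in oil replicate 5 to 504 CPM in oil replicate 1.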
